A study of Homo sapiens with 4 samples.

How the data were processed

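RNA was measured in 4 libraries from cultured human cells, 1 library in each of 4 groups. OPM-2 and KMS-12-BM are multiple myeloma cell lines, and each was present as a variant sensitive to S63845 and as a variant with acquired resistance to it. S63845 is a small molecule that binds and blocks the anti-apoptotic protein MCL-1. Per the labels' protocols, the resistant variants came from more than 1 year of culture in rising doses and were kept in 600 nM, the sensitive variants were long-term culture controls without drug, and drug was withdrawn 2 weeks before RNA was taken. Libraries were made from 800 ng of total RNA with a strand-specific kit that removes ribosomal and globin RNA, and were sequenced as paired reads of 151 bases on an Illumina NovaSeq instrument, per the labels' protocols.

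Each deposited table held, per the file headers, a count for each of 59195 Ensembl gene IDs, with CPM, RPKM and their log2 values made from it by the authors. The counts were whole numbers as deposited, with no scaling, and were the only unit used for the comparisons. The authors' CPM values were scaled to a library size 6.84% to 12.6% above the sum of the counts in the table, and the authors' RPKM values were that CPM per kilobase of a gene length. The deposited log2 values of CPM and RPKM held a prior count of 0.25. The submitters' processing notes name bcl2fastq, edgeR 3.32.0 and limma 3.46.0. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The record of the analysis run inside the KMS-12-BM resistant table was 12 days later than in the other 3 tables. If that record marks a batch, it cannot be told apart from the group, since it covers 1 library. Sample names inside the tables differ from the labels in calling a library DMSO or untreated, and groups were taken from the labels alone.

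Total counts were 92444224 for OPM-2 sensitive, 148286364 for OPM-2 resistant, 128240872 for KMS-12-BM sensitive and 105573140 for KMS-12-BM resistant. Of the gene IDs, 56869 were found in GENCODE 29 on GRCh38, which gave biotypes, positions and exons. That release was chosen for this work and need not be the authors' annotation. Low counts were mostly even: among genes with 1 to 10 counts, 80.4% to 84.1% had an even count in each library, against 49.0% to 50.6% among genes with 1000 to 5000 counts. That is the pattern of tables in which the mates of a pair are counted apart. Intervals from these counts are then too narrow, and limits drawn at 3 counts about 2 times too tight. How reads over overlapping genes were assigned could not be settled from the counts. For 98 non-coding genes with at least 90% of their exonic bases inside exons of an expressed coding gene on the opposite strand, the median count per base was 1.50 times that of the coding gene, and for 109 such genes on the same strand it was 0.168 times. Genes that share exonic bases with another gene, antisense genes and near-identical paralogs are therefore uncertain.

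Per-line comparisons had 1 library per group, so they had no replicate check and no p-value was computed. Counts were scaled with TMM factors over the 4 libraries (0.940, 0.915, 1.07 and 1.08, in the order of the totals above), and CPM values given with the results use the scaled library size. Fold changes are ratios of these CPM values, and log2 fold changes carried a prior count of 2. Each ratio had an exact 95% conditional binomial interval, which covers counting error only. A gene counted as higher or lower when its log2 fold change was at least 1 in size, its CPM was at least 1 in at least 1 of the 2 libraries, and its interval excluded a ratio of 1. Where 1 library had no count, the fold is given as a lower bound, the limit nearer 1 of the 95% interval from halved counts. The effect of resistance common to both lines was tested with edgeR's quasi-likelihood test (robust fit, cell line as a block, Benjamini-Hochberg adjusted p under 0.05), which had 1 residual degree of freedom. The pairing of the libraries comes from the cell line. The 4 libraries showed it: the root mean square log2 difference was 0.813 and 0.767 within OPM-2 and KMS-12-BM, and 2.98 to 3.00 between the lines.

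The design, the alternatives, 44 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change in each line, at 5 CPM or more in the higher library. For the effect common to both lines, fewer than 5 genes passed the test, so the rule took the 10 genes per direction with the largest smaller-of-2 log2 fold change among genes past the size rule in both lines. For opposite changes it took the 5 largest each way. All members of the BCL2 family lists and of the myeloma translocation list were named, efflux transporters past the size rule, and for other lists up to 4 members with the largest change. A few genes that the rule takes are not reported here. Of 749 list symbols, 748 were matched to a row. A list's median log2 fold change was placed among 10000 random lists of the same size matched on expression in 10 bins, as a description of these libraries. Chromosome windows were medians over 25 neighbouring expressed genes, listed at 0.58 or more in size on the log2 scale.

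The procedures were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed in both lines. With no spread beyond counting, the size rule recovered 100% of 4-fold changes in each line and called 0 unchanged genes of 59195. With an added spread of 0.453 in the log2 ratio, the spread seen over genes at 5 CPM or more in both OPM-2 libraries, it called 485 unchanged genes in OPM-2. With an added spread of 0.325, close to that of KMS-12-BM (0.331), it called 46 unchanged genes in KMS-12-BM. With an added spread of 0.636, above that of either line over genes at 5 CPM or more in both libraries, it called 1803 and 1840. The spreads of the lines leave out genes under 5 CPM in a library. Over genes at 1 CPM or more in any library, the root mean square log2 difference was 0.813 within OPM-2 and 0.767 within KMS-12-BM. Both lie above each simulated spread. The test common to both lines recovered 72% of 2-fold increases at a spread of 0.325, 24% at 0.453 and 4% at 0.636. For 4-fold changes it recovered 100%, 100% and 80% of increases, and 100%, 98% and 60% of decreases. It called 10, 9 and 1 unchanged genes at these spreads. The simulated changes were equal in both lines, so these shares do not hold for changes that differ between the lines.

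Alternatives were other scalings (DESeq2 size factors, total counts), prior counts, CPM minimums, fold rules, protein-coding genes alone, and, for the common effect, DESeq2, limma-voom, DESeq2 size factors or total counts in edgeR, no filter on low counts, a fit that was not robust, no block, and each library left out in turn. Scaling within each line's pair, scaling over protein-coding genes, leaving out genes that share exonic bases, halving the counts, and removing a trend on GC content and transcript length from the windows were chosen after seeing the data. Fits with a library left out had no block. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. The authors' CPM, RPKM and log2 values were left out of the comparisons, since they derive from the same counts with a library size that the tables do not explain.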

Results

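Gene expression was measured by RNA sequencing in myeloma cell lines with acquired resistance to the MCL-1 inhibitor S63845 and in their sensitive long-term culture controls. MCL-1 is an anti-apoptotic protein of the BCL2 family, and the comparisons ask which transcripts differ between a resistant variant and its own control. OPM-2 and KMS-12-BM each gave 1 sensitive and 1 resistant library, so each group has n = 1 and no value has a replicate error. The total counts were 92444224 in OPM-2 sensitive, 148286364 in OPM-2 resistant, 128240872 in KMS-12-BM sensitive and 105573140 in KMS-12-BM resistant, and 30246 to 32447 genes had a count above 0. Intervals given with folds are 95% counting intervals of the ratio of 2 libraries. They compare those libraries, not the conditions, and are too narrow where the mates of a pair were counted apart.

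The transcripts that define the lines matched the labels. FGFR3, a receptor kinase gene moved next to immunoglobulin enhancers in some myelomas, was at 1075 and 1119 CPM in OPM-2 sensitive and resistant and at 0.116 and 0.122 CPM in KMS-12-BM. CCND1, the cyclin D1 gene, had no count in OPM-2 sensitive and was at 0.0737 CPM in OPM-2 resistant, against 529 and 376 CPM in KMS-12-BM. CCND2 was at 496 and 399 CPM in OPM-2 and at 0.0145 and 0 CPM in KMS-12-BM. NSD2, a histone methyltransferase gene, was at 1316 and 1002 CPM in OPM-2 and at 289 and 237 CPM in KMS-12-BM. MYC was at 185 and 174 CPM in OPM-2 and at 222 and 256 CPM in KMS-12-BM. CCND3 was at 12.63 and 17.6 CPM in OPM-2 and at 7.85 and 9.35 CPM in KMS-12-BM. Within OPM-2, the transcription factor gene MAF was lower in the resistant library, from 26.6 to 9.51 CPM (2.79-fold, interval 2.61 to 2.99), and it had no count in KMS-12-BM. Of the translocation genes, 2 of 7 expressed in OPM-2 were past 2-fold, both lower, and 0 of 4 in KMS-12-BM.

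In OPM-2, transcripts of several BCL2 family genes were lower in the resistant library while that of the drug target was not. MCL1 was at 684 CPM in the sensitive and 737 CPM in the resistant library. BCL2 (ENSG00000171791, GRCh38 chromosome 18, 63123346 to 63320128), the gene of the anti-apoptotic protein that venetoclax binds, was 2.97-fold lower (91.3 to 30.8 CPM, interval 2.86 to 3.08). BAK1, which encodes a pore-forming pro-apoptotic effector, was 2.74-fold lower (52.6 to 19.2 CPM, 2.61 to 2.87), and BAX was at 19.5 and 13.1 CPM. Of 9 expressed BH3-only genes, whose proteins start apoptosis by binding other family members, 0 were at least 2-fold higher and 2 were at least 2-fold lower. BCL2L11, the gene of BIM, was 3.09-fold lower (22.4 to 7.25 CPM, 2.86 to 3.34) and HRK was 2.80-fold lower (12.63 to 4.52 CPM, 2.53 to 3.09). The other 7 did not pass, with PMAIP1, the gene of NOXA, at 47.1 and 51.1 CPM, BMF at 29.7 and 19.4 CPM and BBC3, the gene of PUMA, at 5.59 and 3.45 CPM. BID was at 8.65 and 9.27 CPM, BAD at 18.9 and 20.8 CPM, BIK at 0.943 and 1.75 CPM and BNIP3L at 38.8 and 22.1 CPM, and BNIP3 stayed under 1 CPM. The median log2 fold change of the list was -0.61, at percentile 0.21 among matched random lists. BCL2L1, the gene of BCL-XL, was at 10.5 and 9.15 CPM and BCL2L2 at 5.66 and 8.63 CPM. Both are uncertain, since 43% of the exonic bases of BCL2L1 and 24.3% of those of BCL2L2 lie in exons of other genes. BCL2A1 and BCL2L10 had 7 counts or fewer in each OPM-2 library, and BOK 3 or fewer. BCL2 was thus the 1 gene past 2-fold of 4 expressed anti-apoptotic family genes.

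The efflux pump gene ABCB1 (GRCh38 chromosome 7, 87503633 to 87713323), known for multidrug resistance, was 46.5-fold higher in OPM-2 resistant (0.0690 to 3.21 CPM, interval 21.2 to 127, or 15.7 to 228 from halved counts). It was the 1 member of 9 expressed efflux transporter genes past the size rule, and ABCG2, another efflux pump gene, was at 7.32 and 13.8 CPM. Among 9 expressed genes that lie beside ABCB1, ELAPOR2 was 2.80-fold higher (7.73 to 21.6 CPM, 2.57 to 3.05) and the other 8 did not pass. Their median was 0.28, at percentile 91.4.

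**Figure D1:**
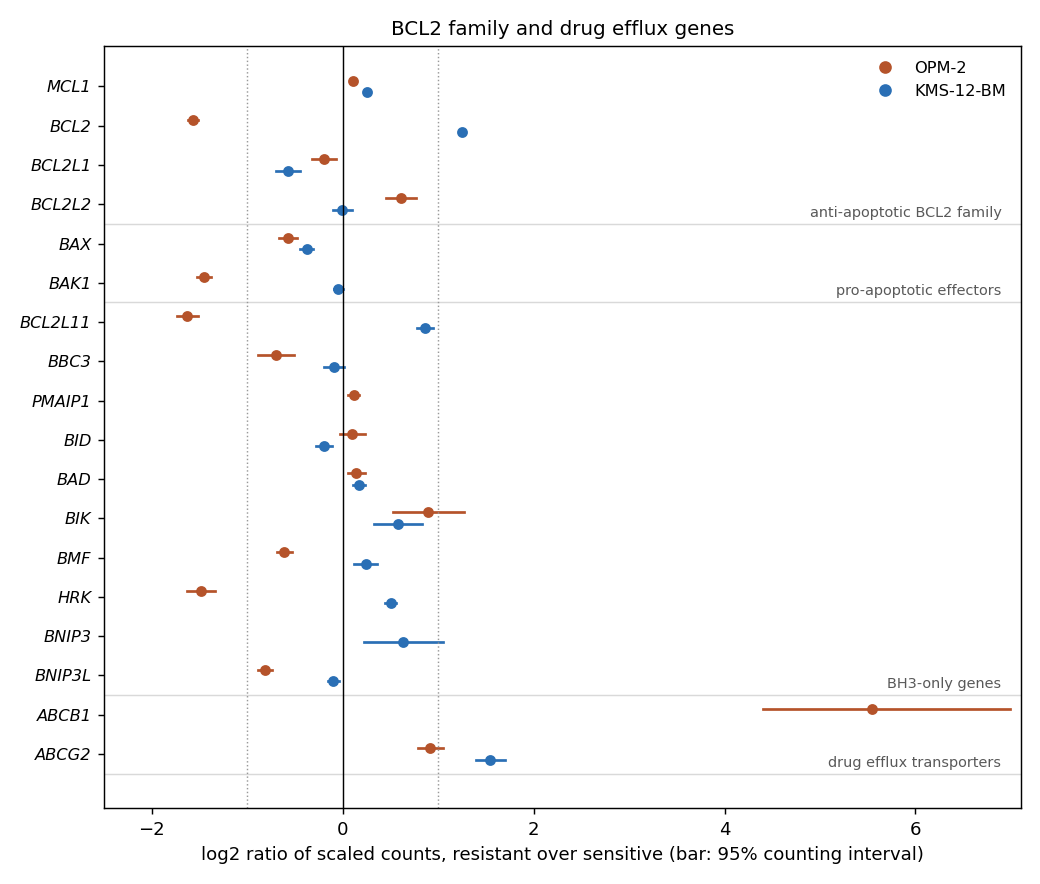
Log2 ratio of scaled counts, resistant over sensitive, for expressed BCL2 family genes and 2 efflux genes in OPM-2 (orange) and KMS-12-BM (blue). The efflux genes shown, ABCB1 and ABCG2, are those past the size rule in a line. Values with no count in a library are left out. Points are ratios of 1 library to 1 library, bars are 95% counting intervals and dotted lines mark 2-fold, with BCL2 at 2.97-fold lower in OPM-2 and 2.38-fold higher in KMS-12-BM.

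Across the transcriptome of OPM-2, 662 genes were at least 2-fold higher and 735 at least 2-fold lower in the resistant library, 9.26% of the 15085 expressed genes, and 35 and 85 were at least 8-fold higher and lower. The largest increase among the named genes was in ANXA1, the gene of the phospholipid-binding protein annexin A1, from 0.897 to 60.2 CPM (67.1-fold, interval 53.7 to 85.0). The cancer-testis gene SSX1 was 43.5-fold higher, the kinase gene ALPK2 38.0-fold, CSRP3 19.995-fold, AZGP1 12.9-fold, GAS7 11.3-fold, the chemokine gene CCL5 10.0-fold, DCT 9.76-fold and CLIC2 9.30-fold. Among the genes that were lower, 6 were at 5 CPM or more in the sensitive library with no count in the resistant one. GSTP1, a glutathione transferase gene, went from 37.0 CPM to no count (at least 679-fold lower) and NACC2 from 24.7 CPM (at least 453-fold). ETFB, the gene of a mitochondrial electron transfer protein, went from 12.8 CPM to no count (at least 234-fold) and MAGEB2 from 10.6 CPM (at least 195-fold). CTD-2616J11.11 (at least 139-fold) is uncertain, since 100% of its exonic bases lie in exons of ETFB. The cancer-testis gene PAGE5 fell from 28.1 CPM to 2 counts (1908-fold lower, 528 to 15761). SORT1 was 355-fold lower, the adhesion molecule gene ALCAM 252-fold, ZNF816 171-fold and EEF1A2 133-fold.

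Many interferon-stimulated genes and NF-kB targets were higher in OPM-2 resistant. Of 22 expressed interferon-stimulated genes, 11 were at least 2-fold higher and 1 was lower, with a median log2 fold change of 1.04 (percentile 100). Examples were RSAD2 (0.460 to 2.90 CPM, 6.31-fold), IFIT2 (0.759 to 3.52 CPM, 4.64-fold) and DDX60 (1.73 to 7.63 CPM, 4.42-fold), and the 1 lower gene was IFIT5 (2.23 to 0.309 CPM, 7.21-fold lower). Of 12 expressed NF-kB targets, 6 were higher and 0 lower, with a median of 1.16 (percentile 100), among them CD83 (7.92-fold), BIRC3 (3.65-fold), the chemokine gene CCL3 (45.8 to 150 CPM, 3.27-fold) and NFKBIE (2.67-fold). Of 15 MHC class I genes, which serve antigen presentation, 5 were higher and 0 lower, with a median of 0.72 (percentile 100), led by ERAP2 (11.8 to 52.6 CPM, 4.45-fold), PSMB9 (3.22-fold), PSMB8 (2.34-fold) and HLA-F (2.30-fold). HLA-F lies in a run of 37 neighbouring genes with a median of 0.41, and with 15 genes per window PSMB8 and PSMB9 lie in a run of 19 genes, themselves included, with a median of 0.37.

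Some plasma cell identity genes were lower in OPM-2 resistant. Of 19 expressed, 0 were at least 2-fold higher and 4 were lower, with a median of -0.35 (percentile 0.2). The signalling adaptor gene LAX1 was 3.73-fold lower (10.0 to 2.70 CPM), the transcription factor gene IRF4 2.28-fold (1138 to 498 CPM, 2.26 to 2.31), SDC1, the gene of CD138, 2.07-fold (610 to 295 CPM) and PRDM1, the gene of BLIMP-1, 2.04-fold (79.8 to 39.2 CPM). Of 8 expressed immunoglobulin genes, 1 was higher and 2 were lower, with a median of -0.79 (percentile 0.02). IGHM was 3.456-fold lower and IGLC1 2.17-fold lower, and IGHA2 was 6.07-fold higher from 0.242 CPM. These genes are near-identical copies of one another and their counts are uncertain. Of 30 cell cycle genes, 0 were past 2-fold in either direction, and their median was 0.30 (percentile 99.9). Of 27 proteasome subunit genes 0 were past 2-fold, with a median of 0.28 (percentile 99.6). Of 39 nuclear-encoded respiratory chain genes, 2 were higher, ATP5MC1 (2.24-fold) and CYC1 (2.15-fold), with a median of 0.22 (percentile 99.4). Of 13 mitochondrially encoded genes, 2 were lower and the median was -0.32 (percentile 0.895). The share of all counts in genes with a symbol that begins with MT- was 1.04% in the sensitive and 0.515% in the resistant library. That share was taken over every such symbol, not over these 13 genes alone. Of 11 expressed hypoxia genes 1 was lower, PDK1 (190 to 92.2 CPM, 2.06-fold), with a median of -0.46 (percentile 0.15).

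The OPM-2 comparison has no replicate, and the number of genes past 2-fold depends on the spread between cultures, which was not measured. Among unchanged genes in simulated libraries, the same rule called 485 at a spread of 0.453 in the log2 ratio. That is the spread seen over genes at 5 CPM or more in both libraries, which leaves out genes that are off in 1 of them. It called 1803, more than in the data, at a spread of 0.636. With a minimum of 5 CPM in place of 1, the real counts were 288 higher and 373 lower.

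In KMS-12-BM, BCL2 was higher in the resistant library, from 199 to 473 CPM (2.38-fold, interval 2.35 to 2.41), and MCL1 was at 201 and 239 CPM. It was the 1 gene past 2-fold of 4 expressed anti-apoptotic family genes, and it lies in a chromosome region where 24 neighbouring genes had a median log2 fold change of 0.65. BAK1 was at 51.4 and 49.8 CPM, BAX at 32.8 and 25.3 CPM and BOK at 0.0291 and 0.324 CPM. Of 9 expressed BH3-only genes, 0 were past 2-fold in either direction, with a median of 0.24 (percentile 98.0). BCL2L11 was at 14.1 and 25.6 CPM (1.82-fold, 1.71 to 1.93) and HRK at 36.3 and 51.4 CPM. BBC3 was at 12.5 and 11.8 CPM, BMF at 7.91 and 9.33 CPM, BID at 19.4 and 16.9 CPM, BAD at 32.0 and 36.0 CPM, BIK at 1.75 and 2.61 CPM, BNIP3 at 0.654 and 1.01 CPM and BNIP3L at 42.0 and 39.1 CPM. PMAIP1 had no count in either KMS-12-BM library, which allows up to 0.0262 CPM (3 counts) in the resistant one. BCL2L1 was at 10.6 and 7.14 CPM and BCL2L2 at 12.64 and 12.598 CPM, with BCL2A1 and BCL2L10 at 15 counts or fewer. ABCG2 was 2.91-fold higher (3.70 to 10.8 CPM, 2.63 to 3.24), the 1 gene past the size rule among 7 expressed efflux transporter genes, with a list median of 0.34 (percentile 99.5). ABCB1 was at 0 and 0.0350 CPM (4 counts).

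Across the transcriptome of KMS-12-BM, 481 genes were at least 2-fold higher and 238 at least 2-fold lower in the resistant library, 4.84% of 14853 expressed genes, and 123 and 24 were at least 8-fold higher and lower. DHRS2 (ENSG00000100867), a dehydrogenase gene, went from 0.465 to 620 CPM (1333-fold, interval 1044 to 1732). The growth factor receptor gene EGFR went from no count to 7.51 CPM (at least 139-fold higher). From no count, the BMP signalling gene SMAD1 went to 6.75 CPM (at least 125-fold) and the polarity gene PARD3 to 6.16 CPM (at least 114-fold). COBL was 612-fold higher (0.0145 to 8.90 CPM, 169 to 5063), FAM19A5 435-fold (0.0872 to 37.9 CPM), TBL1X 385-fold, the phosphatase gene PTPRG 268-fold (0.131 to 35.0 CPM), TRIM68 213-fold and the transcription factor gene TEAD1 206-fold (0.218 to 44.8 CPM). The linker histone gene H1-3, listed as HIST1H1D in the tables, went from 72.8 CPM to 1 count (8318-fold lower, 1493 to 328587). KDM5B, a histone H3 lysine demethylase gene, went from 8.27 CPM to 3 counts (315-fold lower, 108 to 1530). FSTL4 was 83.4-fold lower, SLFN13 74.5-fold, FAM107B 59.4-fold, LAMP5 39.9-fold, CD96 27.8-fold, CLIC2 26.7-fold and AIM1 12.2-fold.

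Some interferon-stimulated genes were also higher in KMS-12-BM resistant, 5 of 20 expressed genes at least 2-fold and 0 lower, with a median of 0.34 (percentile 99.98). IFI44 was 14.9-fold higher (0.523 to 7.81 CPM), IFI44L 6.75-fold, XAF1 3.96-fold and USP18 3.50-fold. Of 14 expressed NF-kB targets, 2 were higher and 0 lower, TNFAIP2 (2.93-fold) and CD40 (2.14-fold), with a median of -0.03 (percentile 54.2). Of 15 MHC class I genes 1 was higher, HLA-E (2.29-fold). Of 11 expressed MHC class II genes 3 were lower, HLA-DQB1 (2.41-fold), HLA-DQA1 (2.27-fold) and HLA-DPB1 (2.18-fold), and the list median was -0.54 (percentile 0). Of 17 expressed plasma cell genes, SEC11C, a signal peptidase subunit gene, was higher (203 to 598 CPM, 2.94-fold) and CD28 (2.71-fold), LAX1 (2.19-fold) and TNFRSF17, the gene of BCMA (199 to 92.5 CPM, 2.15-fold), were lower, with a median of -0.19 (percentile 2.54). Of 22 expressed PI3K, AKT and mTOR genes 2 were lower, among them PIK3CG (95.9 to 27.8 CPM, 3.45-fold), with a median of -0.32 (percentile 0.03). In OPM-2 the same list had 1 lower gene of 21, the mTOR inhibitor gene DEPTOR (2.21-fold), and a median of -0.25 (percentile 0.87). Of 20 expressed cholesterol synthesis genes 1 was lower, NSDHL (2.14-fold), with a median of -0.33 (percentile 0), and in OPM-2 1 of 20 was lower, CYP51A1 (192 to 74.9 CPM, 2.56-fold), with a median of -0.25 (percentile 0.51). Of 35 cytosolic ribosomal protein genes 1 was past 2-fold, RPS16, which was lower against a list median of 0.14 (percentile 100).

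**Figure D2:**
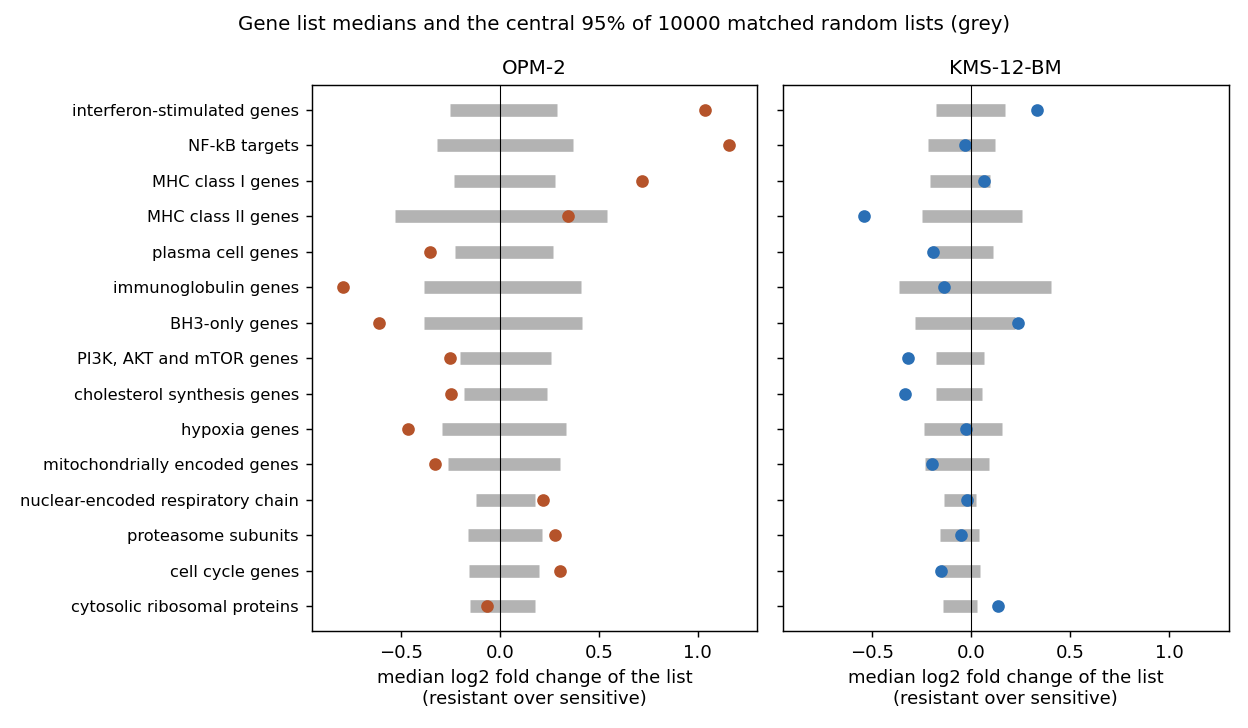
Median log2 fold change, resistant over sensitive, of 15 gene lists in OPM-2 (left) and KMS-12-BM (right). Points are list medians and grey bars the central 95% of 10000 random lists matched on expression, and interferon-stimulated genes lie above the bar in both lines (1.04 and 0.34).

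The KMS-12-BM comparison likewise has no replicate, and the rule called 46 unchanged genes in simulated libraries at a spread of 0.325 in the log2 ratio. That is close to the real spread of 0.331 over genes at 5 CPM or more in both libraries, which leaves out genes that are off in 1 of them. At a spread of 0.636 it called 1840, more than in the data. With a minimum of 5 CPM the real counts were 174 higher and 136 lower. Over both lines, 29 of 80 list medians lay outside the central 95% of their random lists, against 4 expected for lists of independent genes. Genes of a list can move together between any cultures, so the excess does not measure an effect of resistance. The random lists were not matched on GC content or transcript length. Spearman's rho of the log2 fold changes with these was 0.148 and -0.121 in OPM-2 and 0.0945 and -0.0674 in KMS-12-BM. What part of small list shifts comes from these trends was not tested.

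The lines were then compared for changes in common. Of 13004 genes expressed in both, 32 were at least 2-fold higher in both resistant libraries (6.15 expected for independent lists) and 26 at least 2-fold lower in both (5.54 expected). Opposite changes were also more frequent than for independent lists, with 12 genes higher in OPM-2 and lower in KMS-12-BM (4.04 expected) and 24 the other way (8.44 expected). Across these genes, which are not independent replicates, Pearson's r between the log2 fold changes was 0.0721 and Spearman's rho 0.138. The genes higher in both with the largest smaller change were led by AFAP1-AS1 (7.71-fold in OPM-2 and 53.4-fold in KMS-12-BM). It is an RNA antisense to AFAP1 with 7.7% of its exonic bases in another gene. Next came the synaptic vesicle gene SV2B (7.34-fold and 48.8-fold), RP11-57A19.2 (5.79-fold and at least 20.6-fold) and the ephrin gene EFNA5 (4.48-fold and 25.5-fold). The other 6 were KCNK9 (5.06-fold and 3.69-fold), RP11-314O13.1, CAPS2, C1orf61, PAPPA2 and DHRS2 (2.84-fold and 1333-fold).

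KDM5B led the genes lower in both lines (8.52-fold and 315-fold). It was followed by TREML2 (5.64-fold and 3.76-fold), MYD88, the adaptor gene of Toll-like receptors (3.45-fold, 2.90 to 0.840 CPM, and 3.53-fold, 26.2 to 7.42 CPM), and COLGALT2 (3.199-fold and 99.1-fold). The other 6 were RP11-61L19.3, TNS3 (34.4-fold and 2.93-fold), DOCK8 (3.10-fold and 2.90-fold), LAMP5 (2.85-fold and 39.9-fold), RPS16 (2.73-fold and 3.38-fold) and TMSB4X, the gene of thymosin beta 4 (5.82-fold and 2.43-fold). RPS16 went from 483 to 177 CPM in OPM-2 and from 356 to 105 CPM in KMS-12-BM. RPS16 and TMSB4X belong to families with many near-identical copies and are uncertain.

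**Figure D3:**
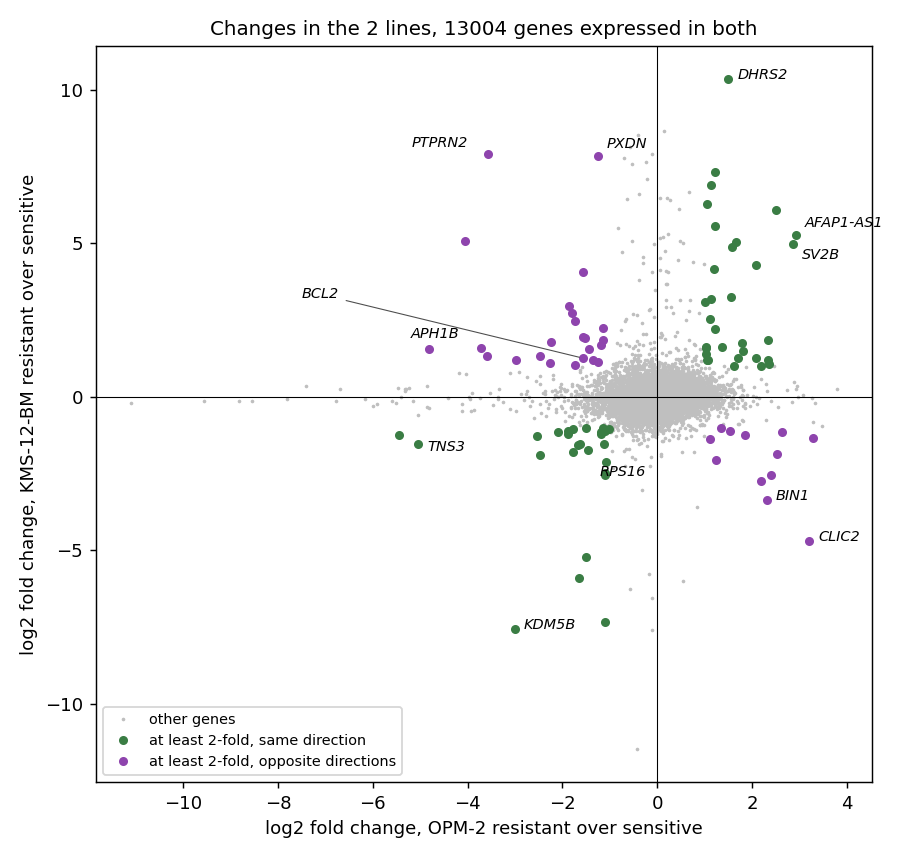
Log2 fold change in OPM-2 (x axis) against KMS-12-BM (y axis) for 13004 genes expressed in both lines, 1 point per gene. Green points are at least 2-fold in the same direction (32 higher and 26 lower) and purple points at least 2-fold in opposite directions (12 and 24).

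A test over the 4 libraries with cell line as a block asked which of these changes exceed the difference between the lines. With edgeR's quasi-likelihood test, 0 of 24752 genes were higher and 0 lower at an adjusted p under 0.05, the smallest adjusted p was 0.995, and 952 genes had an unadjusted p under 0.05, against 1238 expected by chance. limma-voom also called 0 genes, and DESeq2 called 33 higher and 29 lower of 18743. edgeR without a filter on low counts called 160 higher and 83 lower of 39786. Of the 62 genes that DESeq2 called, 17 were among the 58 at least 2-fold the same way in both lines. Adjusted over the list alone, 8 of 28 interferon-stimulated genes passed edgeR's test, each higher in both lines, and 0 passed over all genes tested, where DESeq2 called 3 (IFIT3, IFI44 and IFI44L). The smallest adjusted p over the list alone was 0.0157, shared by IFIT3 (3.51-fold in OPM-2 and 2.84-fold in KMS-12-BM), IFI44, IFI44L and RSAD2. The other 4 were XAF1, USP18, OASL and DDX60. Of the 8, only IFIT3 was past the size rule in both lines, and RSAD2 and DDX60 had 2 and 0 counts in KMS-12-BM sensitive. In 4 other lists of the 44, 1 gene each passed edgeR's test adjusted over the list alone: LAX1 (adjusted p = 0.0492) and RPS16 (0.0119), lower in both lines, RB1 (0.0424), at 1.78-fold lower in OPM-2, where it lies in a run of 64 genes with a median of -0.59, and 2.11-fold lower in KMS-12-BM, and SSX1 (0.0113), higher in both but with 2 and 12 counts in KMS-12-BM. The test rests on 1 residual degree of freedom and 1 library per group, so its only residual is the difference between 2 lines, moderated across genes. A gene silent in 1 line adds little to that residual. The smallest unadjusted p of edgeR's test, 4.93e-05, was that of FAM19A5, which had no count in either OPM-2 library. A small p therefore does not show a change in both lines.

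Neighbouring genes were higher or lower together in parts of several chromosomes. Over windows of 25 neighbouring expressed genes, 283 of 14330 window medians in OPM-2 reached 0.58 or more in size and joined into 18 runs, 8 higher and 10 lower. In KMS-12-BM, 166 of 14110 did and joined into 6 runs, 2 higher and 4 lower. The number depended on the window: with 15 genes per window there were 57 runs in OPM-2 and 16 in KMS-12-BM. In OPM-2 resistant, 110 genes from 276322 to 42699385 on chromosome X had a median log2 fold change of -1.01, among them MAGEB2 and TMSB4X, and 59 genes from 49869033 to 53224879 on chromosome 19 had a median of -0.77, among them ETFB and ZNF816. On chromosome 13, 3 runs of 57, 64 and 44 genes between 27545911 and 106535662 had medians of -0.55, -0.59 and -0.47, and on chromosome 12, 35 genes from 40196744 to 47943048 had a median of -0.34. On chromosome 6, 37 genes from 28121795 to 30346854 had a median of 0.41, and on chromosome 8, 71 genes from 141117278 to 145066685 had a median of 0.61. In KMS-12-BM resistant, 57 genes from 213186 to 23019335 on chromosome 8 had a median of 0.72, and 59 genes from 202133404 to 211675630 on chromosome 1, among them KDM5B, had a median of -0.54. The other 3 lower runs, of 71, 119 and 47 genes on chromosome X, had medians of -0.58, -0.58 and -0.59, and the last held CLIC2. The run with BCL2, 36 genes from 57639455 to 79679358 on chromosome 18, had a median of 0.50 and also held SEC11C. No DNA was measured in these libraries.

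**Figure D4:**
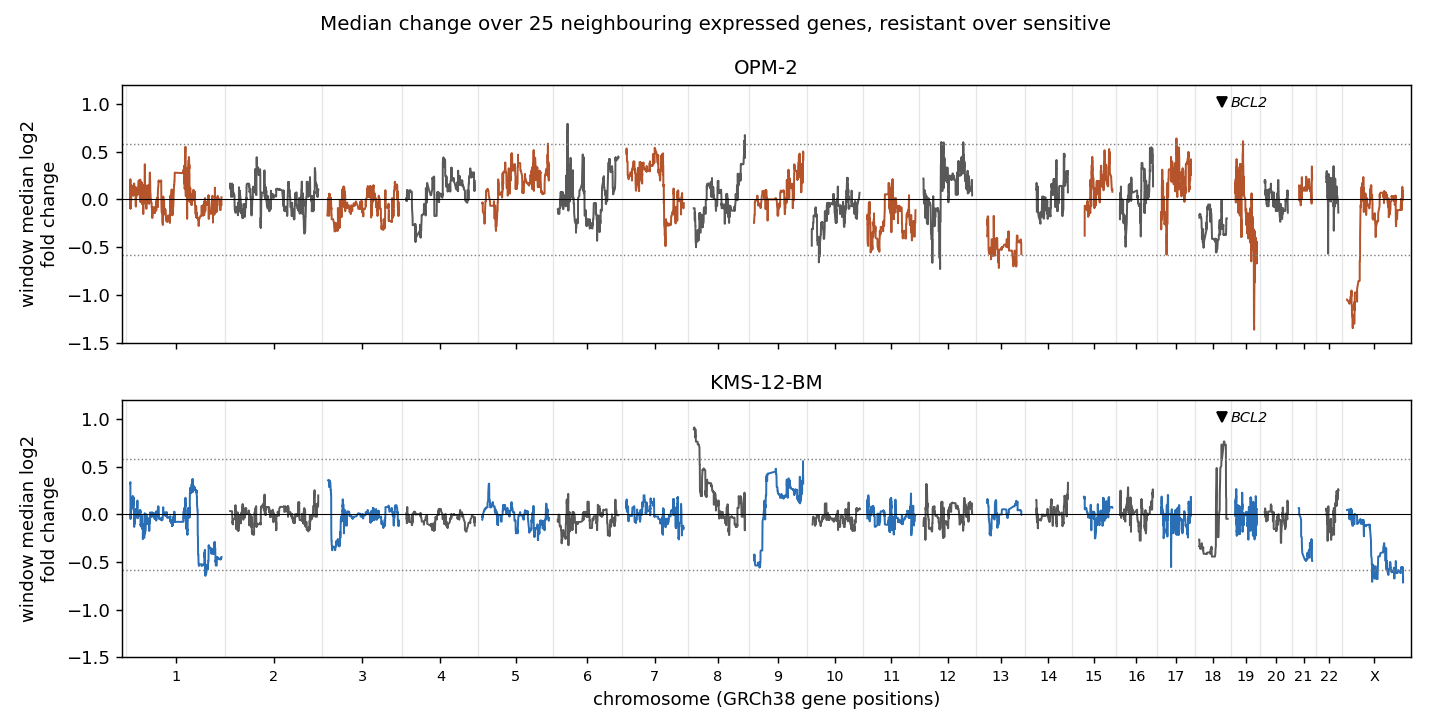
Median log2 fold change, resistant over sensitive, in windows of 25 neighbouring expressed genes along the chromosomes in OPM-2 and KMS-12-BM. Dotted lines mark 0.58 in size and the marker is BCL2 alone, which was lower in OPM-2 (-1.57) and higher in KMS-12-BM (1.25).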

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

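The tests on the order of genes and on the region of BCL2 were chosen after their results were seen, and the test on GC content and transcript length after the windows were seen but before its own result. The results below went in opposite directions in the 2 lines, and the difference between lines was not tested, since each group has 1 library.

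BCL2 was lower in OPM-2 resistant (log2 fold change -1.57) and higher in KMS-12-BM resistant (1.25), a difference of 2.82 on the log2 scale between KMS-12-BM and OPM-2. The chloride channel family gene CLIC2 was higher in OPM-2 (3.21) and lower in KMS-12-BM (-4.72), a difference of -7.92. BIN1 was likewise higher in OPM-2 (2.32) and lower in KMS-12-BM (-3.37), a difference of -5.69. The difference was -4.94 for ZNF723 (2.39 in OPM-2 and -2.55 in KMS-12-BM) and -4.94 for NCALD (2.19 and -2.75). For LY96, which encodes a cofactor of Toll-like receptor 4, it was -4.62 (3.28 and -1.34). PTPRN2 was lower in OPM-2 (-3.57) and at 0 and 4.01 CPM in KMS-12-BM, a fitted difference of 11.5. PXDN was lower in OPM-2 (-1.26) and at 0 and 3.86 CPM in KMS-12-BM, a fitted difference of 9.10. Fitted differences of PTPRN2 and PXDN depend on the prior count, since 1 library had no count. CLEC2L was lower in OPM-2 (-4.06) and higher in KMS-12-BM (5.08), a difference of 9.13. The difference was 6.37 for APH1B (-4.81 and 1.56) and 5.62 for ZNF283 (-1.57 and 4.05). In OPM-2, ZNF723 and ZNF283 lie in runs of neighbouring genes on chromosome 19 with medians of 0.61 and -0.61.

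Chance order of single genes as the cause of the runs of neighbouring genes was argued against for the 5 runs in OPM-2 with a window beyond the largest in 100 random orders (0.707) and for all 6 in KMS-12-BM (0.459), and for the other 13 in OPM-2 only as a set, since no random order gave more than 1 run. Single runs of the 13 may be chance, with these exceptions. The run on chromosome 8 also passed with 50 genes per window (0.610, against 0.398 at most in random orders). Runs of 57 genes on chromosome 13 (-0.55) and of 48 genes from 57571566 on chromosome 19 (-0.61) missed 0.58 at 50 genes. Their medians, over about as many genes, are also beyond 0.398 in size, which argues against chance for them. All 268 expressed genes of chromosome 13 had a median of -0.51. A trend on GC content and transcript length as the whole cause was argued against too for the runs as a set. Without it, a median of 88.6% of a run's shift was kept in OPM-2 and 101% in KMS-12-BM. In OPM-2, 14 of 18 runs kept over 80%. For the others the test did not decide. The run of 35 genes on chromosome 12 kept 56.0%, and the run of 31 genes on chromosome 10 kept 74.9%. On chromosome 13, the runs of 57 and 44 genes kept 73.7% and 67.1%. The shift of its region could account for the whole of the BCL2 change in KMS-12-BM, which lay 0.727 scaled median absolute deviations from the median of its 24 neighbours with 6 of them beyond it, but not in OPM-2, where BCL2 lay at -2.79 of them. Changes in DNA copy number, drift of subclones over more than 1 year of culture and resistance itself stay open, and none was tested.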

How the results depend on the processing

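Scaling within each line, scaling over protein-coding genes, genes that share few exonic bases, counts halved, and the GC and length trend were chosen after seeing the data. No paired analysis was possible within a line because each line has 1 library per group, and the common effect used the cell line as its block, with 0 and 0 genes when the block was left out. Counts of genes are given in the order OPM-2 higher and lower, KMS-12-BM higher and lower, both higher, both lower, OPM-2 higher with KMS-12-BM lower, and the converse. They moved to 2571, 3253, 2681, 1010, 280, 134, 93 and 275 with no CPM filter, and to 288, 373, 174, 136, 8, 9, 2 and 6 with CPM at least 5. They moved to 1967, 1863, 1116, 976, 128, 146, 58 and 109 with a 1.5-fold rule, and to 143, 172, 196, 40, 4, 1, 4 and 2 with a 4-fold rule. These moves follow from which genes each rule admits. The counts stayed within 1.5 times under each other scaling, each prior count, protein-coding genes only, genes that share few exonic bases, and counts halved (664, 715, 471, 237, 31, 27, 12 and 24). The common effect had 33 higher and 29 lower genes with DESeq2 and 160 and 83 with no filter, and the cause was not tested. It had 0 and 0 with limma-voom and under every other setting run. The fits with each library left out in turn also lacked the block, so the difference between the lines entered their residual. Like the fit without the block, they cannot show whether the result holds. Of the 20 genes named for both lines, 10 passed with DESeq2 and 11 with no filter. Of 188 values of named genes, 12 moved with DESeq2 size factors and 10 with total counts alone, by at most 0.04 on the log2 scale. A move was a shift of 50% or more of the width of the counting interval. Under the other scalings and prior counts 0 moved, and 0 reversed. Genes with no count in a library had no finite interval and could not move by this rule. Only genes past the size rule could be called reversed. By more than the range of their random lists, 6 list medians moved with no CPM filter, among them interferon-stimulated genes in KMS-12-BM (0.84), and 2 with CPM at least 5. CPM filters gave no value for single genes. With 15 and 50 genes per window, windows past the size were 498 and 152 in OPM-2 and 222 and 96 in KMS-12-BM, and runs were 57 and 4 in OPM-2 and 16 and 4 in KMS-12-BM, as follows from wider medians. Without the GC and length trend, 208 and 143 windows were past the size. Depth limits genes near 3 counts, and the missing replicates limit the rest.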

Other observations

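The tests on other cells, on counts and on globin, and the grouping of overlapping genes into loci, were chosen after the results were seen.

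Some adhesion and signalling genes also differed between variants, though the list medians lay within the central 95% of random lists: adhesion and homing at percentiles 8.46 in OPM-2 and 45.1 in KMS-12-BM, IL6, JAK and STAT at 82.1 and 5.00, and MAPK output at 96.7 and 94.9. Of 20 expressed adhesion and homing genes in OPM-2, 4 were lower and 0 higher, ICAM3 (13.66-fold), ITGB8 (10.1-fold), ITGB5 (3.25-fold) and PTK2B (2.60-fold), and in KMS-12-BM 2 were higher and 1 lower of 20. Of 14 expressed IL6, JAK and STAT genes in OPM-2, SOCS3 (4.41-fold) and IL2RG (3.71-fold) were higher and the receptor genes IL6R (328 to 129 CPM, 2.55-fold) and IL6ST (2.04-fold) lower. In KMS-12-BM the kinase gene PIM1 was lower (193 to 88.2 CPM, 2.19-fold), as was IL2RG (2.39-fold). Of the MAPK output genes, 3 of 13 expressed were higher and 1 lower in OPM-2, and 3 of 6 were higher in KMS-12-BM, FOS (4.66-fold), PHLDA1 (2.34-fold) and SPRY1 (2.11-fold). The chemokine receptor gene CCR7 was 6.74-fold higher in KMS-12-BM (2.02 to 13.6 CPM) and the glucose transporter gene SLC2A3 21.3-fold higher (0.828 to 17.7 CPM). The B cell receptor gene CD79B was 66.6-fold lower in OPM-2. Of 10 genes that control MCL-1 turnover, 0 were past 2-fold in either line.

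On chromosome 15, from 20379495 to 23630075, a run of 16 genes in KMS-12-BM was chosen after its values were seen. In it 8 pseudogenes or unconfirmed genes were higher in the resistant library, such as NBEAP1 (0.109 to 40.1 CPM, 367-fold) and HERC2P3 (2.27 to 31.6 CPM, 13.9-fold), and 0 of 5 protein-coding genes were past 2-fold. Its copies are uncertain, as near-identical genes share reads.

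Genes under 0.1 CPM in 1 variant of a line and at 5 CPM or more in the other formed a pattern in both lines. Reads or cells of OPM-2 as the source of genes present in KMS-12-BM resistant were argued against, since 23 other genes abundant in OPM-2 and under 0.1 CPM in KMS-12-BM sensitive were present at a median of 0.00395% of their lower OPM-2 level (highest 1.302%), against 3.64% or more of the higher OPM-2 level needed. Too few counts were argued against, since 3 counts stand for 0.0262 CPM or less where such genes were off. The 12 genes off in a resistant variant make 10 loci, and loss of a region that lowers its neighbours was argued against for the set, since the median of the neighbours' medians was -0.11 (interval -0.71 to 0.17). For the 4 loci inside runs of lower genes, ETFB, MAGEB2, ZNF816 and KDM5B, loss of a region stays open (lowest median -0.93), as do loss of a single gene, silencing, and growth of a subclone that never expressed the gene.

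Globin transcripts were counted in all 4 libraries, at 2300 CPM in OPM-2 sensitive, 1461 CPM in OPM-2 resistant, 2426 CPM in KMS-12-BM sensitive and 4266 CPM in KMS-12-BM resistant. Erythroid cells were argued against, since AHSP had no count and ALAS2 reached 0.0295 CPM at most. A common outside source, such as the reagents that remove globin, cannot be told apart from other sources, since the share of a globin gene differed by up to 10.4 percentage points between libraries, between the sizes that would decide.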
